A study of Mus musculus with 31 samples.

How the data were processed

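The study sequenced RNA of peritoneal macrophages of C57BL/6 mice aged 8.5 weeks, collected 4 days after an injection of 3% thioglycollate and cultured overnight. The labels give control mice and mice with a macrophage knockout of PPARγ (KO), 4 of each, and cells left untreated or treated for 24 h with DMSO, with 1 uM rosiglitazone or with 20 ng/mL IL4. There are 31 libraries in 8 groups, 16 of control and 15 of KO cells, with 4 libraries per group and 3 for KO cells with rosiglitazone.

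The deposited table gives FPKM values that the authors made from the reads; their processing notes name TopHat2, featureCounts, edgeR and a mouse genome build, with no versions and without saying which tool made the values. The annotation used here is for another build, so no coordinates are given, and it served only for gene lengths and for the order of genes around Pparg. The table lists 24302 symbols. Of these, 25 are dates, as a spreadsheet makes of some gene symbols; they hold 0.136% of the FPKM and were left out, and 14 of them would have passed the filter.

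Counts of reads are not given in the sources used here. For genes below 0.1 FPKM in both libraries, the ratio of a library to untreated control library 1 was mostly a common step times a ratio of whole numbers up to 5. This held within 0.1% for 64.6% to 76.6% of these genes, against at most 0.4% when the step was shifted. The steps gave relative depths of 0.594 to 1.542, taken as the inverse of the step. Between 8613 and 9913 genes per library had at least 1 FPKM. No interval for counting error was computed.

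Genes with at least 1 FPKM in at least 3 libraries were tested (10327). A linear model with a mean per group was fitted to log2(FPKM + 1) of all 31 libraries with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance, and p was adjusted by the method of Benjamini and Hochberg over genes. A gene passed at an adjusted p under 0.05. The 12 comparisons were KO against control cells in each of the 4 treatments, rosiglitazone against DMSO, IL4 against untreated and DMSO against untreated cells in each genotype, and the difference between the genotypes in the responses to rosiglitazone and to IL4. All tests were two-sided.

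The same fit was repeated after dividing each library by the median of its ratios to the geometric mean of each gene. Values of single genes come from that fit, since the medians of the deposited log2 differences were not 0.

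Gene lists were written from general knowledge: PPARγ target genes, mitochondrial fatty acid oxidation, peroxisomal fatty acid metabolism, IL4 response, inflammatory genes, interferon-stimulated genes, glutamine and glutamate metabolism, tricarboxylic acid cycle, oxidative phosphorylation, glycolysis, cholesterol synthesis, LXR targets, fatty acid and triglyceride synthesis, cell cycle, lysosome, NRF2 and oxidative stress, amino acid starvation and unfolded protein response, MHC class II presentation and macrophage identity. Further lists held markers of resident large peritoneal macrophages, neutrophils, eosinophils, B cells, T and NK cells, dendritic cells, mast cells, mesothelial cells and fibroblasts, and erythroid cells, and sex-linked genes. Some genes stand in 2 lists, such as Cpt1a, Nr1h3, Scd1 and Slc7a11. Lists were tested with camera at a preset correlation of 0.01 and with the correlation estimated, adjusted over the lists of a comparison. Members were also adjusted over the list alone. Overlaps were tested with Fisher's exact test between comparisons without shared libraries. The comparisons come from the same fit, so they share the estimate of spread of each gene, and some share mice. The expected overlaps and Fisher's p assume independent genes and calls, so they are not exact.

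The genes named are Pparg, then in each comparison up to 8 in each direction with the largest absolute log2 difference among those that passed and whose libraries do not overlap, then up to 4 members of each list with the smallest p; predicted models without a gene name were skipped, and some genes that the rule selects are not reported here. With 4 libraries against 4, chance leaves 2.86% of genes without overlap. Names of neighbours of Pparg, of overlapping genes and of Rn45s were chosen after their values were seen. The lists, the tests, this rule and the first set of other settings were fixed before the data were examined.

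The labels number the replicates 1 to 4. Whether a number stands for a mouse was checked by correlating the residuals of libraries with the same number in different treatments. Of the 28 libraries outside KO rosiglitazone, 25 correlated best with their own number. None of the 3 KO rosiglitazone libraries did (0), and all 3 correlated best with the number 1 higher, so blocks by mouse were run as titled and with these libraries matched to mice 2 to 4. The Y-linked gene Ddx3y had 18.31 to 20.54 FPKM in KO libraries numbered 2 outside rosiglitazone, 18.58 in KO rosiglitazone library 1 and at most 0.02872 in the other KO libraries, so the block as titled joins different mice. Each group holds 1 library with Ddx3y and 2 or 3 without.

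Other settings chosen at that time were pseudocounts of 0.1 and 0.01, no filter, at least 5 FPKM, rescaling, quantile normalization, no trend, only the compared groups, array weights, an absolute log2 difference of at least 1, each library left out in turn, blocks by replicate number or mouse, and IL4 against DMSO. Added after the data were seen were rescaling together with a block, leaving out the 3 libraries with low sums or the 5 that list Rn45s at 0, 38 isolated values of 0 in 13 genes set to missing, array weights estimated gene by gene, rescaled list tests and overlaps, and a covariate of mesothelial and fibroblast markers.

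The pipeline was tested on simulated data in which 200 genes were changed. Noise was drawn independently for each gene and library, with no error of library scale and no mouse shared between groups. The rates below hold for such data and not for libraries whose genes deviate together. In the comparison of rosiglitazone with DMSO in control cells it recovered 23.9%, 89.6% and 98.5% of genes changed by log2 differences of 0.5, 1 and 2, with 4.1% false calls, and for the difference of the responses 3%, 47.8% and 98.5%, with 7.5% false calls. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.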

Results

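RNA was sequenced from peritoneal macrophages, drawn into the abdominal cavity with thioglycollate, of control mice and of mice whose macrophages lack PPARγ (KO). PPARγ is a nuclear receptor that binds fatty acid ligands and switches on genes of lipid uptake, storage and oxidation. The cells were left untreated or kept for 24 h with DMSO, which is the vehicle, with rosiglitazone, a synthetic PPARγ ligand, or with IL4, a cytokine that drives the alternative activation of macrophages. The 31 libraries form 8 groups of 4, except that KO cells with rosiglitazone have 3 libraries. Of 24302 listed gene symbols, 10327 passed the filter and were tested. Read totals are not given in the sources used here; from the spacing of the lowest values, the depth of the libraries ranged from 0.594 to 1.542 times that of untreated control library 1, a 2.6-fold range.

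The listed FPKM, which scale fragments by gene length and library size, summed to between 150901 and 306000 per library. The libraries KO untreated 2, KO untreated 3 and control IL4 2 had low sums, at 150901, 166420 and 152055, while the other 28 began at 222091. The 5 libraries control untreated 1, KO untreated 2, 3 and 4 and control IL4 2 listed the ribosomal RNA precursor Rn45s at 0, and the other 26 listed it at 90.2 or more. In the deposited values the median log2 difference over all genes was therefore not 0: it was -0.20 for KO against control untreated cells, 0.21 for IL4 against untreated KO cells and 0.31 for the difference of the IL4 responses. Counts of genes are given as deposited, which was the planned test, and then after each library was rescaled by its median ratio. Single genes are described by their log2 difference in rescaled FPKM plus 1, with the SE and adjusted p of that limma fit, and by rescaled FPKM as mean ± SD.

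**Figure D1:**
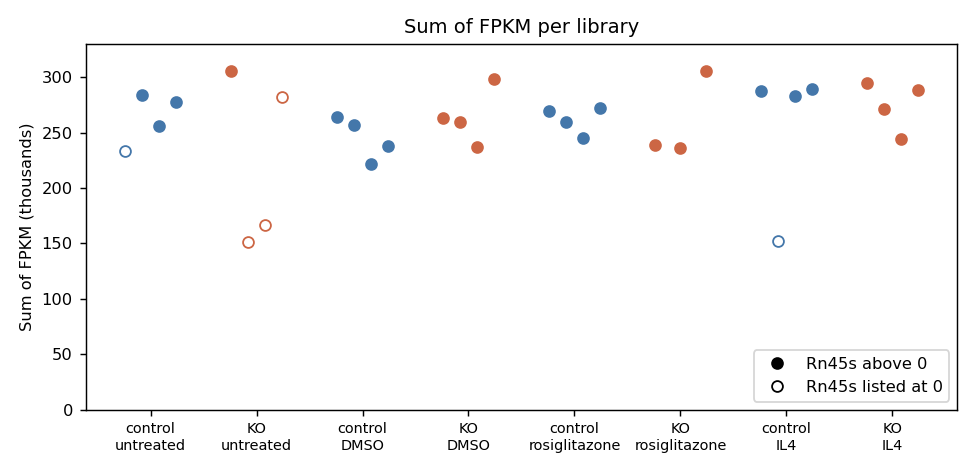
Sum of FPKM per library, in kilo FPKM (vertical axis), for the 8 groups as deposited; each point is a library, and open points list Rn45s at 0. The 3 lowest points lie between 150.9 and 166.4, and the other 28 begin at 222.1.

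The comparison of untreated KO and control cells asks which genes depend on PPARγ without added ligand. Angptl4, a secreted inhibitor of lipoprotein lipase, had 2.56 ± 0.291 FPKM (SD, n = 4) in control cells and 0.402 ± 0.167 in KO cells (n = 4). Plin2, a lipid droplet coat protein, had 547 ± 48.9 FPKM in control and 257 ± 30.2 in KO cells (SD, n = 4), and the fatty acid-binding protein Fabp4 had 443 ± 37.4 and 209 ± 38 (SD, n = 4). Nr1h3, which encodes the oxysterol receptor LXRα, fell from 25.6 ± 0.98 to 7.74 ± 0.258 FPKM (SD, n = 4). The chemokine Cxcl16 was higher in KO cells, at 27.1 ± 1.67 against 12.7 ± 0.875 FPKM (SD, n = 4).

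Of 12 tested PPARγ target genes, 8 fell in untreated KO cells and 0 rose, and 8 fell adjusted over the list alone (camera adjusted p = 8.45e-14, and adjusted p = 0.0274 with an estimated correlation). Their log2 differences included -1.60 ± 0.07 for Nr1h3, -1.35 ± 0.15 for Angptl4 and -1.09 ± 0.10 for Plin2 (SE). The member Cd36 is listed at 0 in KO IL4 library 4. This widens its spread in the fit shared by all comparisons, so the counts of target genes may miss it. In untreated cells Cd36 had 402.8 to 477.1 rescaled FPKM in KO and 894.2 to 1126 in control libraries. Of 20 mitochondrial fatty acid oxidation genes, 4 fell and 8 fell adjusted over the list alone (adjusted p = 0.461 with an estimated correlation, and 0.064 after rescaling). They were Hadhb (-1.20 ± 0.08) and Hadha (-0.77 ± 0.06), the subunits of the trifunctional protein of β-oxidation, Ech1 (-0.66 ± 0.13) and Cpt1a (-0.53 ± 0.12), which carries fatty acids towards the mitochondrial matrix. Of 13 LXR target genes, 3 fell, among them the cholesterol exporter Abcg1 (-0.88 ± 0.11) and the phospholipid-remodelling enzyme Lpcat3 (-0.50 ± 0.08), and 5 fell adjusted over the list alone (adjusted p = 0.461 with an estimated correlation). Of 20 cholesterol synthesis genes, Hmgcs1 fell (-0.46 ± 0.09) and 10 fell adjusted over the list alone (adjusted p = 0.461 with an estimated correlation), and after rescaling 8 fell. The peroxisomal fatty acid transporter Abcd2 (-1.05 ± 0.12), Dgat1 (-0.66 ± 0.07), which makes triglyceride, and glutamine synthetase, Glul (-0.55 ± 0.09), also fell. Of 14 macrophage identity genes, the efferocytosis receptor Mertk (-0.61 ± 0.10) and the IgG receptor Fcgr1 (-0.83 ± 0.16) fell, and 3 fell adjusted over the list alone. Pparg itself had 49.6 ± 2.68 FPKM in control and 45.2 ± 6.11 in KO cells (SD, n = 4; log2 difference -0.14 ± 0.09, limma adjusted p = 0.499). A value per gene cannot show the loss of some exons, and the deleted part of the gene is not given in the sources used here.

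In all, 172 genes passed in untreated cells, 15 higher and 157 lower in KO (8.7% higher), and after rescaling 448 passed, 182 higher and 266 lower (40.6% higher). The excess of lower genes turned with only the libraries of the groups compared (143 higher and 96 lower), with the replicate number as a block (128 and 71) and without the 3 low-sum libraries (132 and 89). That block joins a control and a KO mouse by number alone. In untreated cells the Y-linked Ddx3y had 18.73 rescaled FPKM in control library 1 and 0 in KO library 1. The largest decreases were in Cmbl (-2.71 ± 0.11), Sh2d1b1 (-2.38 ± 0.11), an adaptor of SLAM receptors, and the sorting receptor Sort1 (-2.11 ± 0.16). Among the genes that rose were the integrin Itgb7 (1.34 ± 0.19), Cxcl16 (1.03 ± 0.09) and Serpinb2 (0.87 ± 0.15), an inhibitor of plasminogen activators. Serpinb2 is the member that rose of 4 tested markers of resident large peritoneal macrophages, of which 2 rose adjusted over the list alone (camera adjusted p = 6.18e-07, and adjusted p = 0.00603 with an estimated correlation). The count of 172 became 94, 97 and 103 without control libraries 2, 3 and 4, 113 and 107 without KO libraries 2 and 3, and 397 without KO library 1.

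Of 10 tested markers of mesothelial cells and fibroblasts, which line the cavity, 0 passed over all genes in untreated cells and 8 rose adjusted over the list alone (camera adjusted p = 6.9e-17, and adjusted p = 0.0274 with an estimated correlation, or 0.217 after rescaling). The mean log2 value of these markers was 2.16 ± 0.60 in untreated KO and 0.97 ± 0.73 in untreated control libraries (SD, n = 4). Of 26 cell cycle genes, 0 rose as deposited, also adjusted over the list alone, and after rescaling 4 rose and 11 rose adjusted over the list alone, with a median log2 difference of 0.35 (adjusted p = 0.27 with an estimated correlation, and 0.347 after rescaling). Ccna2, a cyclin, was among the 4 (0.86 ± 0.23).

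**Figure D2:**
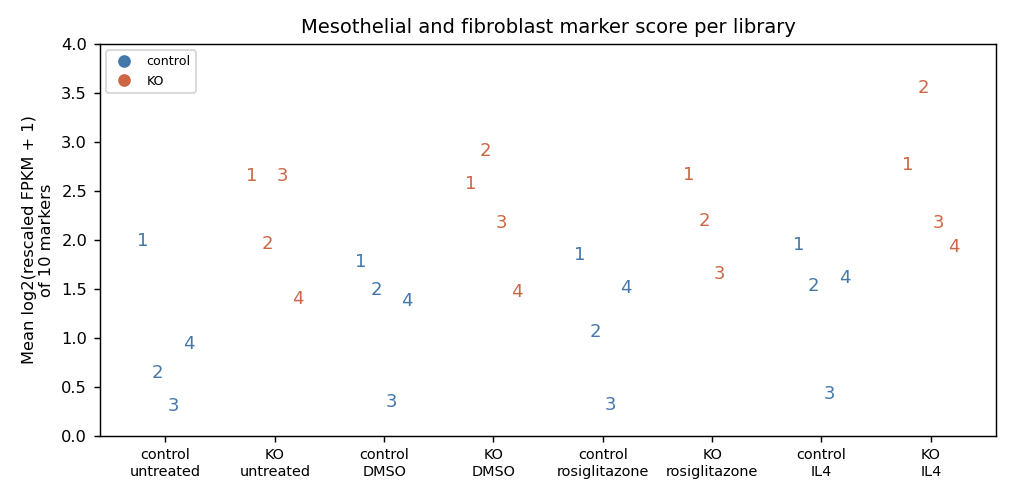
Mean log2 of rescaled FPKM plus 1 over 10 mesothelial and fibroblast markers (vertical axis) for each library, shown by its replicate number, in the 8 groups. The group mean was between 0.97 and 1.38 in control cells and between 2.16 and 2.6 in KO cells.

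With DMSO, the vehicle of rosiglitazone, Nr1h3 had 6.49 ± 0.361 FPKM in KO and 23.2 ± 2.40 in control cells, Angptl4 had 0.312 ± 0.130 and 2.44 ± 0.249, and the organic anion transporter Slco2b1 had 0.0294 ± 0.0153 and 1.95 ± 0.527 (SD, n = 4). The folate receptor Folr2 was higher in KO cells, at 25.7 ± 14.6 against 8.37 ± 1.57 FPKM (SD, n = 4).

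Of the 12 PPARγ target genes, 4 fell with DMSO and 7 fell adjusted over the list alone (camera adjusted p = 3.8e-21, and adjusted p = 0.00906 with an estimated correlation); after rescaling 7 fell. They included Mgll (-1.69 ± 0.30), which splits monoacylglycerol, and Plin2 (-0.98 ± 0.10). Hadhb (-1.07 ± 0.08) was the member that fell of the 20 mitochondrial fatty acid oxidation genes (1 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation), and after rescaling 4 fell. Of 13 inflammatory genes, the costimulatory molecule Cd86 rose (0.65 ± 0.15) and 4 rose adjusted over the list alone (adjusted p = 0.219 with an estimated correlation, and 0.0122 after rescaling). No cell cycle gene of 26 passed over all genes and 16 rose adjusted over the list alone (adjusted p = 0.363 with an estimated correlation). Of the mesothelial and fibroblast markers, 0 passed and 9 rose adjusted over the list alone (adjusted p = 0.279 with an estimated correlation). Their mean log2 value was 2.28 ± 0.62 in KO and 1.25 ± 0.62 in control libraries (SD, n = 4). In all, 121 genes passed, 64 higher and 57 lower (52.9% higher), and 365 after rescaling, 138 higher and 227 lower (37.8% higher). With the replicate number as a block, which joins different mice, 365 passed, 265 higher and 100 lower (72.6% higher). The count of 121 became 65, 67 and 65 without control DMSO libraries 2, 3 and 4, 73 and 60 without KO DMSO libraries 1 and 2, and 189 without KO DMSO library 4.

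With rosiglitazone, Angptl4 had 1.15 ± 0.946 FPKM in KO (SD, n = 3) and 29.2 ± 2.95 in control cells (n = 4), Plin2 had 278 ± 30.4 and 1153 ± 56.3, and Gdf15, a stress-induced cytokine, had 3.37 ± 0.816 and 31.4 ± 6.81 (SD, n = 3 and 4). Cxcl16 was higher in KO cells, at 26.5 ± 1.71 against 5.89 ± 0.594 FPKM (SD, n = 3 and 4).

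Among the PPARγ target genes, 9 fell in rosiglitazone-treated KO cells and 9 fell adjusted over the list alone (camera adjusted p = 4.44e-28, and adjusted p = 0.00202 with an estimated correlation). Of the 20 mitochondrial fatty acid oxidation genes, 7 fell, 10 adjusted over the list alone (adjusted p = 0.235 with an estimated correlation, and 0.0121 after rescaling), among them Hadhb (-1.79 ± 0.09) and Ech1 (-1.54 ± 0.14). Of the 13 LXR target genes, 5 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone (adjusted p = 0.229 with an estimated correlation): Abcg1 (-1.97 ± 0.12), Lpcat3 (-1.52 ± 0.09) and the desaturase Scd2 (-1.27 ± 0.31) were lower, and the cholesterol exporter Abca1 (0.95 ± 0.29) was higher. Of the 13 inflammatory genes, 4 rose, and 8 rose and 1 fell adjusted over the list alone (adjusted p = 0.0638 with an estimated correlation, and 0.00552 after rescaling): the chemokines Ccl4 (1.27 ± 0.15) and Ccl3 (1.01 ± 0.15), Cd86 (0.79 ± 0.16) and Cd40 (0.70 ± 0.16). Of 12 NRF2 and oxidative stress genes, 4 rose, 4 adjusted over the list alone (adjusted p = 0.396 with an estimated correlation): the cystine transporter Slc7a11 (1.11 ± 0.12), Srxn1 (1.04 ± 0.13), Gclm (0.94 ± 0.14) and Nqo1 (0.66 ± 0.13). Of 19 interferon-stimulated genes, 2 rose and 6 rose adjusted over the list alone (adjusted p = 0.341 with an estimated correlation). Of the 20 cholesterol synthesis genes, 2 fell and 3 fell adjusted over the list alone (adjusted p = 0.282 with an estimated correlation), and after rescaling 13 fell. In all, 447 genes passed, 183 higher and 264 lower, and 1211 after rescaling, 521 higher and 690 lower. Of the 26 cell cycle genes, 1 rose and 6 rose adjusted over the list alone (adjusted p = 0.363 with an estimated correlation). The mean log2 value of the mesothelial and fibroblast markers, of which 0 passed either way, was 2.16 ± 0.51 in KO (SD, n = 3) and 1.18 ± 0.67 in control libraries (n = 4).

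With IL4, the chemokine Ccl24, which attracts eosinophils, was higher in KO cells, at 8.26 ± 4.29 against 0.614 ± 0.0901 FPKM (SD, n = 4). Awat1, an acyltransferase that makes wax esters, had 0.184 ± 0.133 FPKM in KO and 17.5 ± 2.27 in control cells, and Slco2b1 had 0.183 ± 0.112 and 12.2 ± 2.33 (SD, n = 4). Fabp4 had 191 ± 19.6 FPKM in KO and 624 ± 36.7 in control cells (SD, n = 4).

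In IL4-treated KO cells 9 of the PPARγ target genes fell and 10 fell adjusted over the list alone (camera adjusted p = 6.3e-34, and adjusted p = 0.000612 with an estimated correlation), among them Gpd1 (-1.05 ± 0.09), which makes glycerol phosphate. Of 12 fatty acid and triglyceride synthesis genes, Dgat1 (-1.50 ± 0.07), Scd1 (-1.61 ± 0.21) and Scd2 (-1.11 ± 0.29) fell, 3 also adjusted over the list alone (adjusted p = 0.196 with an estimated correlation). Of 23 IL4 response genes, 4 rose and 1 fell, and 7 rose and 1 fell adjusted over the list alone (adjusted p = 0.719 with an estimated correlation): Ccl24 (2.41 ± 0.17), the VEGF receptor Flt1 (1.17 ± 0.10) and Ch25h (1.01 ± 0.20) were higher, and the chitinase-like Chil4 (-0.95 ± 0.13) was lower. Of the 13 inflammatory genes, 4 rose and 5 rose adjusted over the list alone (adjusted p = 0.283 with an estimated correlation), among them Ptgs2 (0.64 ± 0.13), the inducible prostaglandin synthase. Of the 10 mesothelial and fibroblast markers, Krt18 and Lrrn4 rose and all 10 rose adjusted over the list alone (adjusted p = 0.214 with an estimated correlation). Their mean log2 value was 2.60 ± 0.72 in KO and 1.38 ± 0.66 in control libraries (SD, n = 4). Of the 26 cell cycle genes, 1 rose, also adjusted over the list alone (adjusted p = 0.719 with an estimated correlation). In all, 448 genes passed, 291 higher and 157 lower (65% higher), and 1119 after rescaling, 523 higher and 596 lower (46.7% higher). The group of control cells with IL4 holds a low-sum library, control IL4 library 2, without which 139 genes were higher and 295 lower (32% higher). Without the 3 low-sum libraries these were 249 and 598 (29.4% higher), and without KO IL4 library 1 the count of 448 became 289.

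Of 15 genes of peroxisomal fatty acid metabolism, 1, 1, 2 and 2 fell in KO cells without treatment and with DMSO, rosiglitazone and IL4, and 1, 2, 3 and 2 fell adjusted over the list alone (adjusted p = 0.754, 0.643, 0.368 and 0.37 with an estimated correlation). After rescaling, 6 fell with rosiglitazone and 6 with IL4 (adjusted p = 0.00552 and 0.00445 with an estimated correlation), among them Abcd2. Of 21 glutamine and glutamate genes, Glul was the member that fell in untreated cells (1 adjusted over the list alone, adjusted p = 0.772 with an estimated correlation). With rosiglitazone 2 rose and 1 fell, and 3 rose and 1 fell adjusted over the list alone (adjusted p = 0.933 with an estimated correlation). With IL4 2 rose and 2 fell, and 5 rose and 2 fell adjusted over the list alone (adjusted p = 0.885 with an estimated correlation). As deposited the 20 lysosome genes passed 0 times in the 4 comparisons of KO with control cells, also adjusted over the list alone; after rescaling 1 rose and 1 fell with rosiglitazone, and 1 rose and 2 fell with IL4. Their member Lipa is listed at 0 in 7 libraries, and its log2 differences as deposited had an SE of at least 2.2; in the libraries with a value it had 545.4 and 554.5 FPKM in untreated KO and 753.1 and 781.1 in untreated control cells. Of 16 glycolysis genes, 1 rose in KO cells with IL4, also adjusted over the list alone (adjusted p = 0.885 with an estimated correlation), and after rescaling 1 rose and 1 fell. Of 3 tested neutrophil markers, 1 fell without treatment, 0 passed with DMSO, 1 rose and 1 fell with rosiglitazone, and 2 rose and 1 fell with IL4 (adjusted p = 0.754, 0.741, 0.919 and 0.818 with an estimated correlation). Adjusted over the list alone, and also after rescaling, 1 more rose without treatment and 1 with DMSO. Of 3 tested eosinophil markers, 0 passed without treatment and with DMSO, 2 fell with rosiglitazone and 2 fell with IL4 (adjusted p = 0.775, 0.61, 0.00809 and 0.00817 with an estimated correlation). These were Ear1 and Ear2, while Siglecf was higher in KO cells with IL4 after rescaling (0.57 ± 0.18) and adjusted over the list alone. None of 5 sex-linked genes passed in any of the 12 comparisons. The lists of B cell, T and NK cell, dendritic cell, mast cell and erythroid markers had 0 members past the filter.

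Across the 4 treatments, 59 genes passed in every comparison of KO with control cells with the same sign, 49 lower and 10 higher in KO, and 225 did so after rescaling, 161 lower and 64 higher. These comparisons share mice and the estimate of spread of each gene, so they do not replicate each other independently. Pparg did not pass in any of the 4 as deposited; after rescaling it was higher in KO cells with rosiglitazone (0.35 ± 0.10, limma adjusted p = 0.0141) and with IL4 (0.28 ± 0.09, limma adjusted p = 0.0432).

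**Figure D3:**
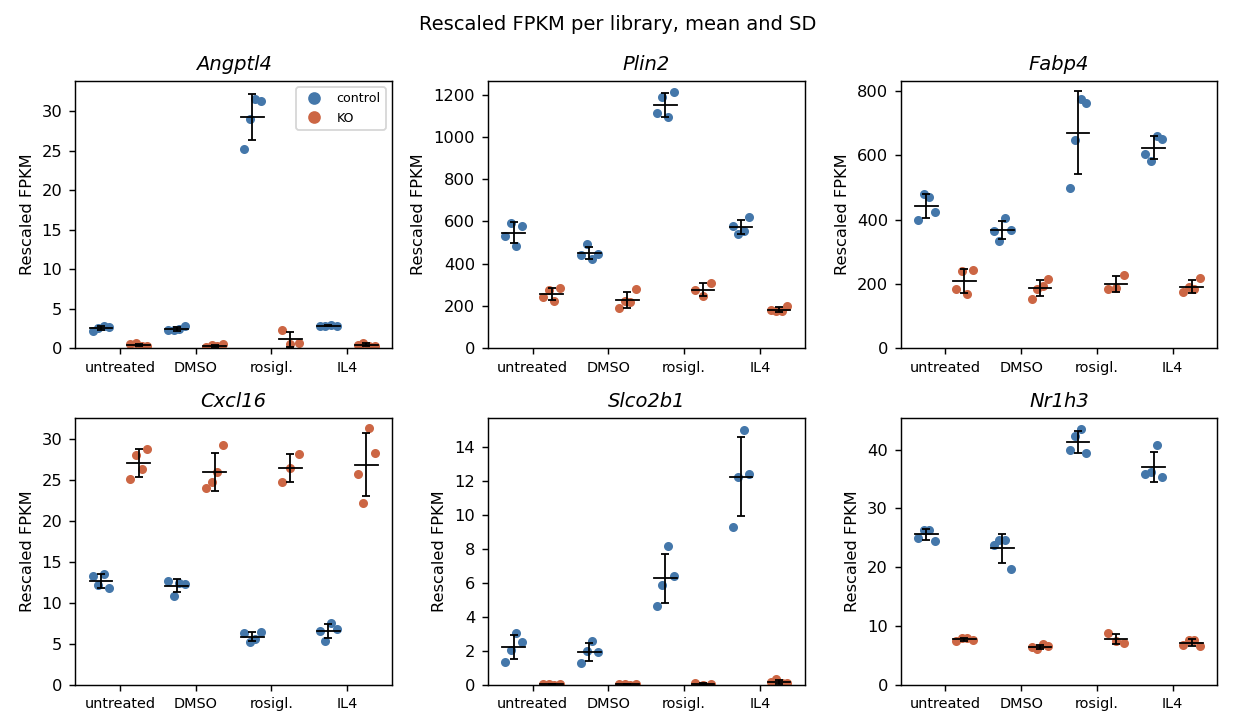
Rescaled FPKM (vertical axes, starting at 0) of 6 genes in control and KO cells without treatment and with DMSO, rosiglitazone or IL4. Each point is a library and the bars are the mean and SD of 4 libraries, or 3 for KO with rosiglitazone. Angptl4 reached a mean of 29.2 in control cells with rosiglitazone and 1.15 in KO cells with rosiglitazone.

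The comparison of rosiglitazone with DMSO asks which genes the ligand changes, and whether this needs the receptor. In control cells, rosiglitazone raised Angptl4 from 2.44 ± 0.249 to 29.2 ± 2.95 FPKM and Plin2 from 451 ± 30.6 to 1153 ± 56.3 (SD, n = 4). Gdf15 rose from 4.67 ± 2.26 to 31.4 ± 6.81 FPKM, and Ear2, a ribonuclease of the eosinophil-associated family, from 0.341 ± 0.145 to 13.1 ± 3.63 (SD, n = 4). Cxcl16 fell from 12.1 ± 0.80 to 5.89 ± 0.594 FPKM and Slc7a11 from 4.59 ± 0.938 to 1.90 ± 0.282 (SD, n = 4).

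Of the 12 PPARγ target genes, 5 rose in control cells and 9 rose adjusted over the list alone (camera adjusted p = 2.77e-30, and adjusted p = 0.000634 with an estimated correlation), among them Angptl4 (3.13 ± 0.15), Plin2 (1.35 ± 0.10) and the triglyceride lipase Pnpla2 (1.24 ± 0.14). Cd36, whose spread in the fit is widened by a listed 0, had 724.4 to 895 rescaled FPKM with DMSO and 1623 to 2080 with rosiglitazone. Of the 20 mitochondrial fatty acid oxidation genes, 3 rose, 8 adjusted over the list alone (adjusted p = 0.239 with an estimated correlation, and 0.00915 after rescaling): Ech1 (1.15 ± 0.13), Cpt1a (0.95 ± 0.12) and Acaa2 (0.92 ± 0.13). After rescaling, 11 rose. Of the 13 LXR target genes, Lpcat3 (1.23 ± 0.08), Abcg1 (0.92 ± 0.11) and Nr1h3 (0.81 ± 0.07) rose, and 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.239 with an estimated correlation, and 0.0308 after rescaling). Abca1 differed by -0.94 ± 0.27, which passed only after rescaling (limma adjusted p = 0.0401, and 0.123 as deposited). Of the 14 macrophage identity genes, the lipopolysaccharide receptor Cd14 fell (-0.88 ± 0.10), and 1 rose and 1 fell adjusted over the list alone (adjusted p = 0.924 with an estimated correlation). Other genes that rose were Ear10 (1.71 ± 0.15), the transcription factor Fos (1.43 ± 0.16) and the complement receptor C5ar1 (1.43 ± 0.23), and Arl4c (-1.10 ± 0.10) and the metalloprotease Adam8 (-0.85 ± 0.08) fell. Of 3 tested eosinophil markers, Ear1 and Ear2 rose, both also adjusted over the list alone (camera adjusted p = 5.24e-14, and adjusted p = 0.000455 with an estimated correlation); reads of Ear genes can be shared between these close paralogs. In all, 91 genes passed, 80 higher and 11 lower (87.9% higher), and 461 after rescaling, 321 higher and 140 lower (69.6% higher). With the mouse as a replicate block 192 passed where the KO rosiglitazone libraries are matched to mice 2 to 4, and 1387 after rescaling with that block. The count of 91 became 59 without control rosiglitazone library 1. Pparg differed by -0.39 ± 0.09 (limma adjusted p = 0.00805, and 1 as deposited).

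In KO cells, limma called 0 genes between rosiglitazone and DMSO, as deposited and after rescaling, where 37 and 151 genes had an unadjusted p under 0.05. With array weights it called 2352 genes, in an estimate that did not converge, 49 with weights estimated gene by gene, and 4 after rescaling with such weights. After rescaling with the mouse as a replicate block, and these libraries matched to mice 2 to 4, limma called 0. Angptl4 had 1.15 ± 0.946 FPKM with rosiglitazone (SD, n = 3) and 0.312 ± 0.130 with DMSO (n = 4), and the 3 libraries with rosiglitazone had 2.231, 0.4999 and 0.7063 FPKM. Of the 12 PPARγ target genes, 0 passed over all genes and 1 rose adjusted over the list alone (camera adjusted p = 5.36e-06, and adjusted p = 0.837 with an estimated correlation, or 0.00909 after rescaling), with a median log2 difference of 0.16 after rescaling.

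The difference of the rosiglitazone responses, KO minus control, passed for 19 genes, all negative, and after rescaling for 83, of which 11 were positive and 72 negative. A positive difference can be a lost decrease: Cxcl16 differed by 0.95 ± 0.14, and fell with rosiglitazone in control cells by 0.93 on the log2 scale. At pseudocounts of 0.1 and 0.01 the count of 19 became 6 and 2. With the mouse as a replicate block, and the KO rosiglitazone libraries matched to mice 2 to 4, 33 passed. The largest were Ear2 (-3.32 ± 0.35), Angptl4 (-2.51 ± 0.22), Gdf15 (-1.83 ± 0.33), Ear10 (-1.65 ± 0.23), B3gnt7 (-1.31 ± 0.16) and Slco2b1 (-1.25 ± 0.22). Of these, Ear2, Angptl4, Gdf15 and Ear10 passed at a pseudocount of 0.1 and Ear2 at 0.01. Among the PPARγ target genes, 1 passed over all genes and 7 adjusted over the list alone, all negative (camera adjusted p = 2.75e-23, and adjusted p = 0.00296 with an estimated correlation); after rescaling 6 passed. Of the 20 mitochondrial fatty acid oxidation genes, 0 passed and 6 passed adjusted over the list alone (adjusted p = 0.449 with an estimated correlation, and 0.0105 after rescaling). The count of 19 became 12 without control DMSO library 4 and 11 without KO rosiglitazone library 2.

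**Figure D4:**
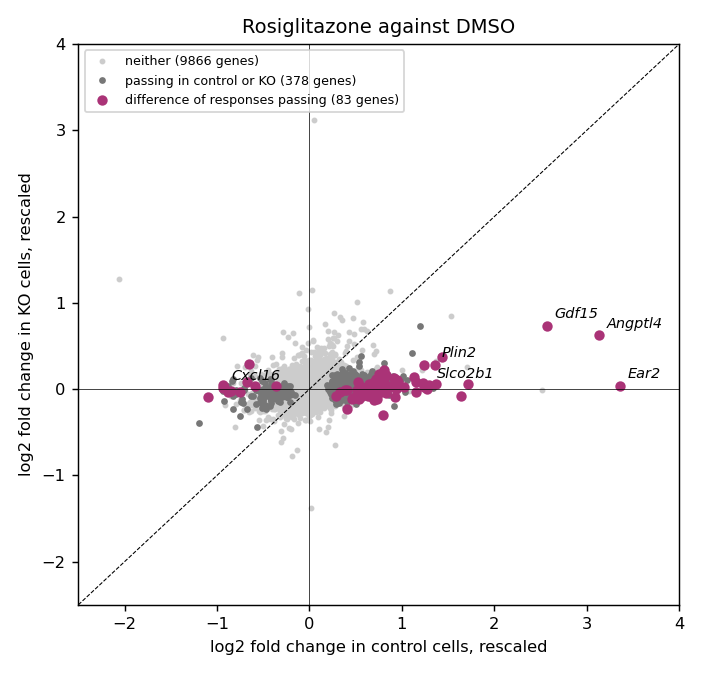
Log2 fold change of rosiglitazone against DMSO in control cells (horizontal axis) and KO cells (vertical axis) for 10327 genes, rescaled. Each point is a gene, coloured points are the 83 genes whose responses differ, and the dashed line marks equal change. Ear2 lies at 3.36 in control cells and its response is lower by a log2 difference of -3.32 in KO cells.

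IL4 against untreated cells asks how alternative activation proceeds with and without PPARγ. In control cells, IL4 raised the chitinase-like protein Chil3 from 7.28 ± 2.41 to 6340 ± 1090 FPKM, arginase 1, Arg1, from 0.316 ± 0.254 to 84.8 ± 38.3, and Retnla from 4.50 ± 3.02 to 287 ± 193 (SD, n = 4). In KO cells, Chil3 rose from 7.03 ± 3.72 to 3323 ± 385 FPKM, Arg1 from 0.662 ± 0.374 to 99.7 ± 40.9, and Retnla from 3.21 ± 3.35 to 322 ± 179 (SD, n = 4). Pparg rose from 49.6 ± 2.68 to 97.1 ± 5.06 FPKM in control and from 45.2 ± 6.11 to 119 ± 13 in KO cells (SD, n = 4).

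Of the 23 IL4 response genes, 19 rose in control cells and 21 adjusted over the list alone (camera adjusted p = 1.32e-73, and adjusted p = 3.02e-06 with an estimated correlation), and 22 rose in KO cells, also 22 adjusted over the list alone (adjusted p = 6.85e-06 with an estimated correlation). All but 1 of the 8 MHC class II presentation genes rose in control cells and all 8 in KO cells, and 8 in both adjusted over the list alone (adjusted p = 0.0507 and 0.289 with an estimated correlation). They included the transactivator Ciita, at 1.55 ± 0.18 in control and 1.20 ± 0.18 in KO cells. Of 15 genes of amino acid starvation and the unfolded protein response, 4 rose in control cells, and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.403 with an estimated correlation, and 0.0211 after rescaling), among them the chaperone Hspa5 (1.02 ± 0.09); 5 rose in KO cells and 9 adjusted over the list alone (adjusted p = 0.941 with an estimated correlation). Of the 12 fatty acid and triglyceride synthesis genes, Scd1 (1.84 ± 0.21), Scd2 (1.88 ± 0.29) and Dgat1 (1.01 ± 0.07) rose in control cells, and 6 adjusted over the list alone (adjusted p = 0.353 with an estimated correlation), while 2 rose in KO cells and 5 adjusted over the list alone (adjusted p = 0.941 with an estimated correlation).

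Of 29 oxidative phosphorylation subunits, 0 passed in control cells, also adjusted over the list alone, and 15 rose after rescaling, 18 adjusted over the list alone (adjusted p = 0.737 with an estimated correlation, and 0.376 after rescaling). In KO cells 7 rose and 22 adjusted over the list alone (adjusted p = 0.941 with an estimated correlation), and 10 after rescaling. Of 20 tricarboxylic acid cycle genes, Idh3a rose in control cells (0.81 ± 0.08), the 1 also adjusted over the list alone (adjusted p = 0.737 with an estimated correlation), and after rescaling 14 rose and 1 fell. In KO cells 3 rose and 10 adjusted over the list alone (adjusted p = 0.941 with an estimated correlation). Of the 26 cell cycle genes, 3 rose in control and 6 in KO cells, and 10 and 22 adjusted over the list alone (adjusted p = 0.403 and 0.941 with an estimated correlation); the mesothelial marker Krt18 rose too, by 0.79 ± 0.17 in control and 1.17 ± 0.17 in KO cells. Of the 20 cholesterol synthesis genes, 2 rose in control and 6 in KO cells, and 5 and 12 adjusted over the list alone (adjusted p = 0.569 and 0.941 with an estimated correlation), among them Dhcr7 (1.11 ± 0.10 and 0.84 ± 0.10). As deposited, the median log2 difference over all genes was -0.10 in control and 0.21 in KO cells. List counts as deposited with IL4, here and above, therefore do not show which genotype responded more.

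Other transcripts fell with IL4. In control cells these included the C-type lectins Clec4d (-2.24 ± 0.13) and Clec12a (-2.14 ± 0.17), the interleukin 1 antagonist Il1rn (-1.83 ± 0.29) and the oxidase subunit Cybb (-1.44 ± 0.20), and in KO cells Clec4d (-1.68 ± 0.13), Clec4e (-1.67 ± 0.16), C5ar1 (-1.57 ± 0.23) and Il1rn (-1.52 ± 0.29). Cd14 fell in both, by -1.39 ± 0.10 and -1.36 ± 0.10. Of the 13 inflammatory genes, Ccl4 (-1.08 ± 0.14) and Ccl3 (-1.06 ± 0.14) fell in control cells, and 2 rose and 4 fell adjusted over the list alone (adjusted p = 0.822 with an estimated correlation). In all, IL4 changed 698 genes in control cells, 285 higher and 413 lower (40.8% higher), and 2373 after rescaling, 1231 higher and 1142 lower (51.9% higher). In KO cells it changed 862 genes, 739 higher and 123 lower (85.7% higher), and 2015 after rescaling, 1046 higher and 969 lower (51.9% higher). With the mouse as a replicate block, and the KO rosiglitazone libraries matched to mice 2 to 4, 1260 and 1789 genes passed. Against DMSO in place of untreated cells, 746 genes passed in KO cells, 354 higher and 392 lower, of which 427 were among the 862. The 3 low-sum libraries belong to these groups. Without them IL4 changed 1386 genes higher and 527 lower in control cells, and 390 higher and 947 lower in KO cells, and the count of 862 became 2766 and 568 without KO untreated libraries 1 and 2 and 519 without KO IL4 library 1.

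The IL4 responses overlapped between the genotypes, with 251 genes higher in both (20.4 expected by chance, Fisher's exact p = 1.81e-264) and 102 lower in both (4.92 expected, Fisher's exact p = 6.43e-126). The difference of the responses, KO minus control, passed for 24 genes, 14 positive and 10 negative, and after rescaling for 72, 26 positive and 46 negative. At pseudocounts of 0.1 and 0.01 the count of 24 became 2 and 0. With the mouse as a replicate block 80 passed with the KO rosiglitazone libraries matched to mice 2 to 4, and 41 as titled, which joins different mice. Larger in KO cells were the increases of Ccl24 (2.35 ± 0.23), the ribonuclease Rnase2a (1.44 ± 0.19), the amino acid oxidase Il4i1 (0.99 ± 0.16) and Flt1 (0.95 ± 0.14). Cxcl16 (0.85 ± 0.13) fell with IL4 in control cells by 0.86 on the log2 scale and differed by -0.02 in KO cells. Smaller in KO cells, in log2 of FPKM plus 1, were the increases of Awat1 (-2.85 ± 0.15), Ear2 (-2.20 ± 0.34), Ear10 (-1.93 ± 0.22), Slco2b1 (-1.87 ± 0.21), Angptl2 (-1.81 ± 0.28), B3gnt7 (-1.59 ± 0.15) and Gpd1 (-1.06 ± 0.13). These sizes depend on the pseudocount where levels in KO cells are near 0. Of the 12 genes named, Awat1 and Ccl24 passed at a pseudocount of 0.1 (limma adjusted p = 0.0241 for both) and 0 at 0.01. From 0.1 to 0.01, as deposited, Awat1 went from -2.46 to -1.08, Slco2b1 from -1.33 to -0.395, and Ear2 and Ear10 turned from -0.67 and -1.58 to 1.11 and 0.40 (limma adjusted p = 0.494 and 0.828 at 0.01). Among the PPARγ target genes, Gpd1 passed, also adjusted over the list alone (camera adjusted p = 3.17e-15, and adjusted p = 0.0258 with an estimated correlation), and after rescaling 3 passed, all negative.

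**Figure D5:**
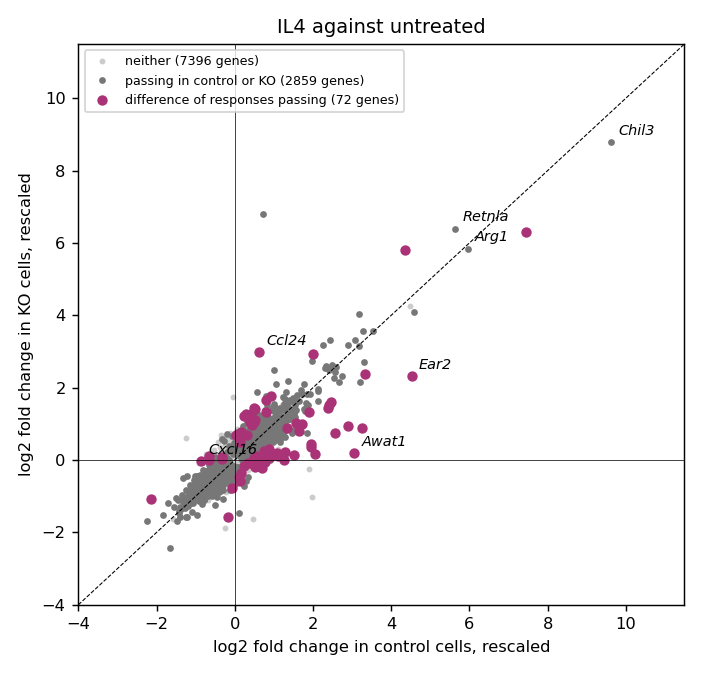
Log2 fold change of IL4 against untreated cells in control (horizontal axis) and KO cells (vertical axis) for 10327 genes, rescaled. Each point is a gene, coloured points are the 72 genes whose responses differ, and the dashed line marks equal change. Chil3 lies at 9.62 in control and 8.79 in KO cells.

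Rosiglitazone and IL4 shared part of their targets in control cells. Of the 80 genes raised by rosiglitazone, 17 were also raised by IL4 (2.21 expected, Fisher's exact p = 4.12e-11), among them Awat1, B3gnt7, Dgat1, Slco2b1 and 4 Ear genes, and 6 of 11 lowered genes were also lowered by IL4 (0.44 expected, Fisher's exact p = 1.54e-06), among them Cd14 and Cxcl16. Of the same 80 genes, 43 were among the 157 lower in untreated KO cells (1.22 expected, Fisher's exact p = 7.25e-59), among them Abcg1, Angptl4, Nr1h3, Plin2 and Sort1. Of the 11 lowered by rosiglitazone, 2 were higher in untreated KO cells, Cxcl16 and Phlpp1 (0.02 expected, Fisher's exact p = 0.000107). No gene was shared between the rosiglitazone responses of control and KO cells, since 0 passed in KO cells.

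DMSO against untreated cells compares the vehicle with no treatment; the time untreated cells were kept is not given in the sources used here, so it is not separated from the vehicle. Limma called 0 genes in control and 0 in KO cells, as deposited and after rescaling. An unadjusted p under 0.05 was found for 114 genes in control and 2636 in KO cells as deposited, and for 681 and 512 after rescaling. With array weights limma called 630 and 5799 genes, with weights estimated gene by gene 43 and 3119, and after rescaling with such weights 6 and 862. With the mouse as a replicate block 8 and 8 passed with the KO rosiglitazone libraries matched to mice 2 to 4, 3 and 3 as titled, which joins different mice, and 169 and 137 after rescaling with the matched block. Without KO untreated library 1 the count in KO cells became 4639. Angptl4 had 2.44 ± 0.249 FPKM with DMSO and 2.56 ± 0.291 without in control cells (SD, n = 4), and Cxcl16 had 12.1 ± 0.80 and 12.7 ± 0.875 (SD, n = 4).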

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

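The tests of read shares and depth, of the correlation among markers, and of the Ear genes were chosen after the results were seen, and the marker covariate was added after the data were seen, with its tests set before their own outcome was known. The first test of the Ear genes counted values of 0 and could not come out either way, so it was replaced by the test of ratios after its outcome was known.

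The 3 libraries KO untreated 2, KO untreated 3 and control IL4 2 had low values across genes. As to lower sequencing depth, 0 of the 3 had a relative depth below the lowest of the other 28. That depth comes from the step of the same FPKM values, so it follows the total used to scale them. It does not give the number of reads in the genes of the table, so fewer reads in these genes stay open. Reads counted in the library total but absent from the table cannot be told apart from another error of scale: FPKM times gene length accounted for 53.2%, 67.1% and 55.5% of the total in these 3 libraries and for 88.3% to 109.1% in the 26 libraries that list Rn45s above 0, but this share is made from the same low values. Of the 5 libraries that list Rn45s at 0, 4 lay below 88.3%, among them these 3. What set the scale stays open, and no biological explanation was tested.

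Markers of mesothelial cells and fibroblasts, a list of 12 fixed beforehand of which 10 were tested and 0 are in another list, had a higher mean in KO libraries, with Col1a2 at 18.4 ± 11.7 and Dcn at 17.3 ± 11.9 FPKM in untreated KO cells and 3.95 ± 5.35 and 6.02 ± 6.31 in untreated control cells (SD, n = 4). RNA of such cells in the cultures may be their source, which stays open. The markers varied together within groups, with a median correlation of 0.85 against a 95th percentile of 0.19 among 10000 random lists. Those lists were matched on expression alone, so genes regulated together in any cell would also exceed them. RNA of such cells as the source of the lower PPARγ target genes is argued against, since 32 of 34 calls were left with the marker score as a covariate. For the cell cycle genes it stays open, as their median log2 difference in untreated cells went from 0.35 to -0.01 with the covariate. Whether the genotype or the single mice set the score stays open: the mean per mouse without rosiglitazone libraries was 1.90, 1.22, 0.36 and 1.31 in control and 2.66, 2.81, 2.33 and 1.60 in KO mice (difference 1.15, exact permutation p = 0.057, n = 4).

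Ear genes were higher with rosiglitazone and with IL4 in control cells. Prg2, abundant in eosinophils, goes against eosinophil RNA, as it was at 0 FPKM in the 8 libraries and above 0 in 2 others. The table also lists some expressed genes at 0, and Epx, at 0 in all 31 libraries, adds nothing. Siglecf, another marker on the eosinophil list, was at 3.278 to 8.041 FPKM in the 8 libraries. In control libraries without treatment or with DMSO it had 4.721 to 9.618 FPKM. Eosinophil RNA is therefore not excluded. Reads of Ear2 alone counted for its paralogs too cannot be told apart from a change of each gene: 0 of 3 ratios to Ear2 differed between the treatments, with exact permutation p of 0.114 for Ear1, 0.457 for Ear3 and 0.714 for Ear10 (0.342, 0.686 and 0.714 after adjustment, n = 4). A response of Ear2 itself in macrophages stays open and was not tested further.

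The response to rosiglitazone differed between the genotypes for 19 genes, and the response to IL4 for 24, each by a test of the difference itself. Among 35 regroupings of the mice, the highest other count was 1 for rosiglitazone and 2 for IL4 at the pseudocount of 1. Every other regrouping put control and KO mice in the same group, so differences between the genotypes added to the spread. This lowers the other counts whether or not the responses differ, so the regroupings do not exclude chance. At pseudocounts of 0.1 and 0.01 the real grouping gave 6 and 2 genes for rosiglitazone and 2 and 0 for IL4.

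Of 168 sets of 4 libraries tested, 12 held a library far from the other 3, and chance gives about 1 in 20. In rescaled FPKM, control IL4 library 3 had 2.95 for Angptl4, where the others had 2.80 to 2.82. It also had 40.8 for Nr1h3 (others 35.4 to 36.2), 0.481 for Ccl24 (others 0.638 to 0.669) and 14.2 for Awat1 (others 18.3 to 19.1). Control rosiglitazone library 3 had 1.39 for Awat1 (others 2.00 to 2.12). KO DMSO library 2 had 0.0258 for Awat1, and the others were at 0. KO IL4 library 4 had 197 for Plin2 (others 175 to 178), and KO IL4 library 1 had 46.6 for Itgb7 (others 30.5 to 32.7). KO DMSO library 4 had 12.6 for Chil3 (others 4.64 to 5.67). KO untreated library 4 had 8.19 for Retnla (others 0.904 to 2.08), and KO untreated library 1 had 3.93 for Slc7a11 (others 4.86 to 4.95). The values of Chil3 and Retnla followed the mouse outside IL4. Chil3 had 12.3 in KO untreated library 4 and 13.0 in KO rosiglitazone library 3, which matches mouse 4. Retnla had 8.02 in KO DMSO library 4 and 7.84 in KO rosiglitazone library 3. The sum of FPKM of control IL4 library 2, in kilo FPKM, was 152.1, where the others had 283.1 to 289.3.

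Of the 14 symbols that are dates and had at least 1 FPKM in 3 libraries, some passed: 1, 3 and 2 between KO and control cells without treatment, with rosiglitazone and with IL4, 1 with rosiglitazone in control cells, 4 and 2 with IL4 in control and KO cells, and 1 for the difference of the rosiglitazone responses.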

How the results depend on the processing

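The settings chosen after the data were seen are those that combine rescaling with a block, weights, a marker covariate or an estimated correlation, the matched block where it had not been fixed for a comparison, those that leave out 3 or 5 libraries or set isolated values of 0 to missing, the rescaled list tests and overlaps, and weights estimated gene by gene. The cause was not tested for any count below, except that an added fold limit leaves fewer genes by construction. A stricter filter tests fewer genes, 6820 at 5 FPKM or more, but can also call new ones. For IL4 in KO cells it called 684 genes, of which 633 were shared with the call as deposited. Counts are given in the order KO against control cells without treatment, with DMSO, with rosiglitazone and with IL4, then rosiglitazone in control and KO cells, IL4 in control and KO cells, DMSO in control and KO cells, and the differences of the rosiglitazone and the IL4 responses, unless named. As deposited these were 172, 121, 447, 448, 91, 0, 698, 862, 0, 0, 19 and 24. Counts stayed within 1.5 times of these for all 12 comparisons without the trend and with isolated values of 0 set to missing, and with IL4 against DMSO (862, 746 and 27 for IL4 in control and KO cells and the difference). In KO cells that control turned the direction, from 739 higher and 123 lower to 354 and 392, with 427 genes shared. With the mouse as a random block, KO against control gave 182, 138, 457 and 465. Relative depth lay between 0.594 and 1.542, and read counts, which would set the precision of low values, are not given in the sources used here.

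Rescaled, the counts became 448, 365, 1211, 1119, 461, 2373, 2015, 83 and 72, leaving out the comparisons with 0. Quantile normalization gave 403, 398, 1163, 1108, 482, 2358, 2151, 91 and 62 for the same. Array weights gave 5892, 1836, 3784, 2729, 1973, 2352, 4424, 5543, 630, 5799, 1797 and 982 in an estimate that did not converge. Estimated gene by gene they gave 2267, 1426, 2255, 2336, 1477, 49, 3839, 3232, 43, 3119, 483 and 167. Rescaled with such weights the counts were 933, 872, 2714, 2703, 1480, 4, 4020, 3311, 6, 862, 270 and 193. Rescaled with the marker score as a covariate, KO against control gave 276, 321, 1145 and 861, and rescaled with the mouse as a random block 564, 467, 1500 and 1246.

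With only the groups compared, KO against control gave 197 with DMSO and 676 with rosiglitazone, rosiglitazone in control cells 319, IL4 in KO cells 494, DMSO 1 and 16, and the rosiglitazone difference 69. At least 5 FPKM left 60 genes for KO against control with DMSO and 246 with IL4, 47 for rosiglitazone in control cells, and 8 and 9 for the differences. An absolute log2 difference of at least 1 left 60, 42, 208 and 151 for KO against control, 26 for rosiglitazone in control cells, 204 and 249 for IL4, and 13 for the IL4 difference. Without a filter the IL4 difference had 46 genes. A pseudocount of 0.1 left 6 and 2 genes for the differences. A pseudocount of 0.01 left 78 for KO against control with DMSO, 50 for rosiglitazone in control cells and 2 and 0 for the differences, and it reversed Ear2 (1.11) and Ear10 (0.40) in the IL4 difference.

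The replicate number as a block, which joins a control and a KO mouse by number alone, gave 365 for KO against control with DMSO. The mouse as titled, which joins different mice in KO cells with rosiglitazone, gave 3 and 3 for DMSO and 41 for the IL4 difference. With the KO rosiglitazone libraries matched to mice 2 to 4, the block gave 192 for rosiglitazone in control cells, 1260 and 1789 for IL4, 8 and 8 for DMSO, and 33 and 80 for the differences. Rescaled with that block these were 1387, 3928, 3672, 169, 137, 369 and 291, and rosiglitazone in KO cells gave 0. Without the 3 libraries with low sums, KO against control gave 472, 983 and 847 with DMSO, rosiglitazone and IL4, rosiglitazone in control cells 326, IL4 1913 and 1337, and the differences 92 and 49. Rescaled without the 5 libraries that list Rn45s at 0, the counts were 355, 1245 and 957 for the same KO comparisons, 434 for rosiglitazone and 1901 for IL4 in control cells, and 79 for the rosiglitazone difference. Only KO untreated library 1 is left of its group there, so counts that use that group are not given.

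Leaving out each library in turn gave 94 to 397 for KO against control without treatment (94, 97 and 103 without control 2, 3 and 4, 113 and 107 without KO 2 and 3, 397 without KO 1). With DMSO it gave 60 to 189 (65, 67 and 65 without control 2, 3 and 4, 73, 60 and 189 without KO 1, 2 and 4), with rosiglitazone 318 to 394, and with IL4 289 to 443 (289 without KO IL4 1). Rosiglitazone gave 59 to 73 in control cells (59 without control rosiglitazone 1) and 0 to 0 in KO cells. IL4 gave 494 to 835 in control cells and 519 to 2766 in KO cells (2766 and 568 without KO untreated 1 and 2, 519 without KO IL4 1). DMSO gave 0 to 0 in control cells and 0 to 4639 in KO cells (4639 without KO untreated 1). The differences gave 11 to 16 for rosiglitazone (12 without control DMSO 4, 11 without KO rosiglitazone 2) and 16 to 36 for IL4.

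Of the list tests, 115 passed at the preset correlation, 19 with the correlation estimated and 35 rescaled with it estimated. The overlaps of rosiglitazone with IL4 went from 17 and 6 genes to 116 and 72 rescaled and to 6 and 0 with an absolute log2 difference of at least 1. Those of rosiglitazone with the untreated KO comparison went from 43 and 2 to 129 and 38, and to 11 and 0. Those of IL4 between the genotypes went from 251 and 102 to 757 and 698, and to 106 and 17. Of 332 gene results that passed and are named by the rule, 329 kept their direction and passed after rescaling, 324 with quantile normalization, 296 and 281 at pseudocounts of 0.1 and 0.01, 292 without a filter, 279 with only the groups compared and 213 with the fold limit.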

Other observations

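The tests of the 80 genes raised by rosiglitazone were chosen after the results were seen, and the test of genes near Pparg and the regroupings of libraries were chosen before.

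Some lists changed in part with IL4. In control cells 2 of 15 genes of peroxisomal fatty acid metabolism rose, among them Abcd2 by 1.31 on the log2 scale (camera adjusted p = 0.00812, and 0.737 with the correlation estimated), and 3 rose in KO cells. Of 19 interferon-stimulated genes 2 fell in control cells, Oas3 by 1.44 and Irf7 by 0.77. Of 12 NRF2 and oxidative stress genes 2 fell, Cat by 0.62 and Gclm by 0.57. Of 14 macrophage identity genes Cd14 fell by 1.39. Of 13 LXR target genes 2 rose and 1 fell in control cells, and 4 rose and 1 fell in KO cells. Of 16 glycolysis genes 0 passed with limma in control cells (4 rose after rescaling) and 2 rose in KO cells. As deposited, the median log2 difference over all genes was -0.10 in control and 0.21 in KO cells. The counts as deposited therefore do not show which genotype responded more.

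A hypothesis is that KO cells kept a small response of the genes that rosiglitazone raises in control cells. In KO cells 55 of these 80 genes were above 0 with rosiglitazone, with a median rescaled log2 difference of 0.04 against 0.81 in control cells (camera p = 0.000102, correlation estimated). As deposited, 43 of the 80 were above 0 with a median of 0.01, where the median over all genes was -0.08. Camera was not run on these genes as deposited. The rescaled values go with a residual response, while 0 single genes passed with limma, where 37 had an unadjusted p under 0.05 as deposited. The source of such a response was not tested. Camera was run without a block by mouse. KO cells with DMSO also hold a library of mouse 1, while the KO rosiglitazone libraries match mice 2 to 4. A difference of that mouse could therefore add to the small median. The same genes were chosen on libraries of control cells that the comparison in KO cells does not share.

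A further hypothesis is that these genes respond less to IL4 without PPARγ. The difference of the IL4 responses had a median of -0.30, with 69 of the 80 below 0 (camera p = 1.9e-11, correlation estimated). With IL4 their median was 0.21 in control cells, with 59 above 0, and -0.09 in KO cells, with 31 above 0. This is consistent with a part of the IL4 response that depends on the receptor, found and tested on the same data. Levels near 0 in KO cells lower such a difference at the pseudocount of 1, and other pseudocounts were not run for these 80 genes.

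Genes near Pparg could differ between the mice through a passenger or local effect of the knockout. Of 28 tested neighbours, 4 passed in any of the 4 comparisons of KO with control cells (14.3%, against 6.6% of the 10327 genes tested; Fisher's exact p = 0.111). They were Vhl, Mbd4, Plxnd1 and Tmcc1, and Tmcc1 passed in 3 comparisons as deposited and in all 4 after rescaling. The bound set before the test took a p of 0.05 or more as an exclusion; that was wrong, because 28 neighbours are too few for a missed threshold to exclude the effect, so the passenger or local effect cannot be told apart from other sources.

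Each comparison was set against the other splits of its libraries into groups of the same sizes, 35 in all with the real one. Without treatment, KO against control had 172 genes as deposited, and 4 splits gave as many, so chance cannot be excluded. The highest other, 4783, parted the libraries that list Rn45s at 0 from the rest, which points to a structure of the samples. Rescaled, the real split gave 448 and the highest other 1, so chance is argued against. IL4 in KO cells had 862 as deposited, and 3 splits gave as many, the highest other 2661, which parted mice 1 and 4 from mice 2 and 3, a structure of the samples. Over these 35 splits chance cannot be excluded as deposited, while rescaled the real split was the largest, with 2015 against 997. These libraries pair by mouse, so the 35 splits do not exclude chance after rescaling either. Among the 8 splits that part every pair, too few for a share under 0.05, 862 stood against a highest other of 0.

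Chance is argued against for the following comparisons of KO with control cells, where the real split alone, 1 of 35, was the largest. That is the smallest share these splits can give, and it was not adjusted for the number of comparisons, which share mice. As deposited and rescaled, KO against control gave 121 and 365 with DMSO (highest other 1 and 7), 447 and 1211 with rosiglitazone (136 and 629), and 448 and 1119 with IL4 (45 and 8). The real split was also the largest for rosiglitazone in control cells, with 91 and 461 (1 and 12). The same held for IL4 in control cells, with 698 and 2373 (274 and 1). Libraries of these treatments pair by mouse, so the 35 splits do not exclude chance for them. The rescaled differences gave 83 for rosiglitazone and 72 for IL4 (1 and 1). Their other regroupings put both genotypes in the same group, which adds to the spread, so chance is not excluded for them. The 8 splits that part every pair of libraries of a mouse are too few for a share under 0.05. Among them the highest other was 0 for rosiglitazone in control cells and for IL4 in KO cells, and 214 as deposited for IL4 in control cells.

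With 0 genes in the real split, all 35 splits give as many by construction, so the splits say nothing about rosiglitazone in KO cells (highest other 1 as deposited and 2 rescaled), DMSO in control cells (2 and 1) and DMSO in KO cells (3173 and 3155). In limma 37, 114 and 2636 genes had an unadjusted p under 0.05 as deposited in these, and array weights gave 2352, 630 and 5799. For DMSO in KO cells the split with 3173 parted the libraries numbered 1 and 4 from those numbered 2 and 3, and the split with 3155 put KO untreated 1, 2 and 4 with KO DMSO 4, which follows no label. Splits that call so many genes point to a structure of the samples.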
